A study of Mus musculus with 10 samples.

How the data were processed

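Salivary gland tissue of female NOD/ShiLtJ mice (10 samples) was digested with dispase II and collagenase IV and filtered to isolate cells. Total RNA was extracted with Trizol, both per the labels' protocols. Biotin-labelled sense cDNA was hybridised to Affymetrix arrays. The deposited values are log2 intensities per probe set, which the authors normalized between arrays with RMA in Affymetrix Power Tools, per the submitters' processing notes. The versions of both, the RMA settings and any probe set filter are not given in the sources used here. The time of day of collection and the gland taken are not given there either.

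The value table held 41345 probe sets. A gene table for the array named 25335 of them, of which 23521 had 1 gene symbol (22180 distinct symbols) and 1814 had several, and 16010 were unnamed here. Of the probe sets with 1 symbol, 23328 matched a mouse RefSeq annotation by gene identifier, which changed 0 symbols, and 193 did not match. The annotation was used for names only, so no positions are given. Probe sets with 1 symbol were kept where the value exceeded the array's own 25th percentile in at least 3 arrays, and the probe set with the highest mean over all arrays stood for each gene (911 genes had several). This left 18826 genes.

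Groups were taken from the labels: diabetic at 21 weeks (n = 4), nondiabetic at 21 weeks (n = 3) and nondiabetic at 6 weeks (n = 3). All 10 arrays entered 1 linear model with a mean per group, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 7 residual and 5.61 prior degrees of freedom). The 3 differences between groups were tested two-sided with limma's moderated statistic, and p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. The median log2 change over all genes was 0.04 for diabetes, −0.06 for age and −0.02 for both together, and each scaling alternative moved it by less than 0.1.

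The groups, the tests, 41 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The lists covered cell types of the gland and of neighbouring tissues, immune signals, metabolism, stress and saliva secretion, and 40 of them had at least 5 measured members. The erythroid list had 3 measured members and was not tested. Lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 40 lists of a comparison, and again with an estimated correlation and with fry, which tests whether a list's genes move on balance 1 way without setting them against other genes. The members past the gene test were counted over all genes and adjusted over the list alone. Some genes stand in more than 1 list.

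Named genes were, for each comparison, the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, without predicted models and antigen receptor segments, filled to 6 per direction by the smallest p where fewer passed. To these came the 4 members with the smallest p of each list that was called or held a gene past the threshold, and a set of fixed genes where they were measured. Not all genes that this rule admits are named in the text. Antigen receptor segments were counted together, 22 of them.

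The steps were tested on simulated data with planted changes. A log2 change of 1 was recovered for 83%, 74% and 78% of genes in the comparisons of diabetes, age and both, and a change of 2 for 99%, 100% and 100%, with 9, 3 and 11 false calls among 191, 177 and 189. A planted list was called and 0 random lists were. The simulated genes varied independently, so this does not test camera where the genes of a list move together. In the real arrays the estimated correlation within a list was as high as 0.74 (B cells). The first principal component held 33.9% of the variance and the second 16%, and 0 pairs of arrays were identical.

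Alternatives were no filter and a filter at each array's median, the mean of a gene's probe sets, every probe set, a fit of only the 2 groups compared, trended and robust variance, array weights, quantile normalization, median centring, an adjusted p under 0.01, a change of at least 2-fold, the replicate number as a block, and each array left out in turn. Leaving out both arrays that stand apart and a parotid cargo covariate, the mean of Amy1, Dnase1, Chia1 and Cst10, were chosen after seeing the data. For each comparison, every split of the arrays of both groups into the same sizes was fitted in the same way (35 or 10 splits). The probe sets with several symbols or unnamed here were left out of the comparisons, since their gene is unclear.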

Results

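Gene expression was measured on 10 arrays, each from the salivary gland cells of a female NOD/ShiLtJ mouse, a strain that develops autoimmune diabetes and inflammation of the salivary glands. The mice fell into 3 groups: 4 with type 1 diabetes at 21 weeks of age, 3 without diabetes at 21 weeks and 3 without diabetes at 6 weeks. The labels number the mice of each group separately, so each array was read as a separate mouse. The p-values of single genes below are set against the spread between these mice. Camera's p-values with the preset correlation treat the genes of a list as nearly independent. They therefore do not measure how well a list's shift repeats between mice. Camera's p-values with an estimated correlation allow for genes of a list that move together. The labels name the salivary gland and not which gland was taken. After filtering, 18826 genes were tested, and the number of arrays limits the precision of each value. Array 3 of the nondiabetic 21-week group stood apart, with correlations of 0.901 to 0.93 with the others against 0.94 to 0.975 among the other 9 arrays. Changes are given on the log2 scale with the standard error of the limma fit, and adjusted p-values are from that fit unless camera, limma's test of gene lists, is named.

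The first comparison set the diabetic mice (n = 4) against nondiabetic mice of the same age (n = 3), the contrast named in the series text. Secreted proteases of the granular convoluted tubule, the duct segment of the mouse submandibular gland that stores growth factors and kallikreins, were far lower in the diabetic glands. Klk1b8 fell about 67.1-fold (log2 change −6.07 ± 0.46, adjusted p = 0.00015) and Klk1b22 fell 25-fold (−4.64 ± 0.66, adjusted p = 0.0049). On 3 of the 4 diabetic arrays Klk1b8 lay below the array's 25th percentile, close to background, so its fold is not exact. The gene of epidermal growth factor, Egf, fell 4.87-fold (adjusted p = 0.000663). Cargo genes of serous cells rose in the same arrays, with Chia1, a chitinase, up 78.7-fold (6.30 ± 0.76, adjusted p = 0.00151) and Amy1, salivary amylase, up 37.6-fold (5.23 ± 0.55, adjusted p = 0.000519). Without nondiabetic array 3 the Chia1 rise was 143-fold. Cxcl13, a chemokine that draws B cells into lymphoid follicles, rose 10.2-fold (3.35 ± 0.48, adjusted p = 0.00482), and Pdk4, a kinase that restrains glucose oxidation, rose 4.44-fold (2.15 ± 0.22, adjusted p = 0.000519).

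Of the 17 measured granular convoluted tubule genes, 12 fell, 0 rose and 5 did not pass the test, and 14 fell when adjusted over the list alone (median log2 change −2.76). Klk1b9 fell 23.6-fold, Klk1b16 21.9-fold, Klk1b21 9.43-fold, Klk1b11 9.1-fold, Crisp3 9-fold, Klk1b24 6.76-fold and Klk1b27 4.87-fold. Klk1b1 fell about 21-fold, with 2 of the 4 diabetic arrays below the 25th percentile. The list was called down by camera (adjusted p = 1.03e-25), with adjusted p = 0.0996 with an estimated correlation. The kallikrein genes of this family are near copies of each other, so single members could not be separated with certainty by hybridisation. Fads2b, outside the lists, fell 4.99-fold (−2.32 ± 0.32, adjusted p = 0.00414).

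Among the 19 measured serous acinar and secretory cargo genes, 8 rose, 0 fell and 11 did not pass, and 11 rose when adjusted over the list alone (median log2 change 1.97). Smr3a, a submaxillary and parotid secretory peptide, rose about 138-fold (7.11 ± 1.25, adjusted p = 0.0155), Cst10 about 68.5-fold, Dnase1 36.1-fold and Bpifa2, the parotid secretory protein, about 6.56-fold. Smr3a and Cst10 each lay below the 25th percentile on 1 of the 3 nondiabetic 21-week arrays. The diabetic values of Bpifa2 (12.30 to 12.38) lay near the lowest array maximum of 13.13, so these 3 folds are not exact. Camera called the list up (adjusted p = 9.16e-08), with adjusted p = 0.0996 with an estimated correlation. Aqp5, the water channel of acinar cells, had a log2 change of 0.10 ± 0.16 (adjusted p = 0.814) and Bhlha15, a regulator of secretory cells, −0.28 ± 0.18 (adjusted p = 0.47). Bpifb1 rose 19.3-fold, Odam 7.37-fold and Serpinb11 5.83-fold. A score of cargo abundant in the parotid gland, the mean of Amy1, Dnase1, Chia1, Cst10, Smr3a and Bpifa2 chosen after their values were seen, lay between 10.28 and 10.74 in the diabetic arrays. It was 4.48, 4.28 and 6.68 in the nondiabetic 21-week arrays and 8.66, 4.85 and 6.76 in the 6-week arrays.

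**Figure D1:**
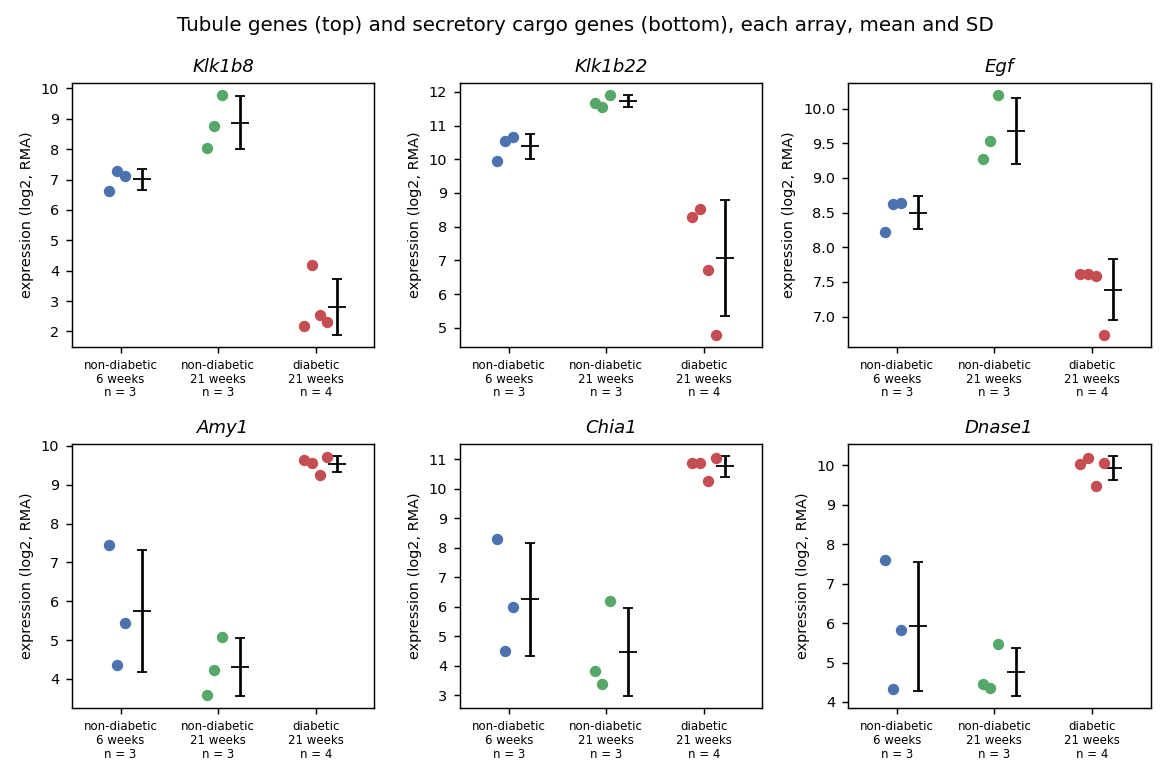
Expression (log2, RMA) of 3 tubule genes (Klk1b8, Klk1b22, Egf) and 3 cargo genes (Amy1, Chia1, Dnase1) on each array, with group means and standard deviations, for 6-week nondiabetic (n = 3), 21-week nondiabetic (n = 3) and 21-week diabetic mice (n = 4). Klk1b8 averaged 2.80 in the diabetic and 8.87 in the nondiabetic 21-week arrays, and Amy1 9.54 and 4.31.

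Of the 11 measured mucous and sublingual genes, 1 rose, Galnt12, an enzyme of mucin glycosylation (1.43 ± 0.32, adjusted p = 0.0458), 0 fell and 10 did not pass, and 3 rose when adjusted over the list alone. Camera called the list up (adjusted p = 0.0229; adjusted p = 0.399 with an estimated correlation). Muc19, the main mucin of the sublingual gland, had a log2 change of 5.51 ± 1.44 (adjusted p = 0.0853), and its values in the nondiabetic 21-week arrays were 2.03, 10.86 and 4.70, the first below the 25th percentile, so this difference is not exact. Among 19 duct epithelium genes, 2 fell, 0 rose and 17 did not pass, while 8 fell and 4 rose when adjusted over the list alone. Scnn1b, a sodium channel subunit, fell 2.17-fold (adjusted p = 0.00328) and Ascl3, a regulator of duct cells, 2.36-fold (adjusted p = 0.0104). The duct list was called down by camera (adjusted p = 0.00281; adjusted p = 0.399 with an estimated correlation). The contractile genes Acta2 (1.26 ± 0.25, adjusted p = 0.0288) and Myh11 (0.91 ± 0.17, adjusted p = 0.0243) were the 2 of 9 myoepithelial and basal cell genes that rose, 0 fell and 7 did not pass, and 3 rose when adjusted over the list alone. The myoepithelial list was called up by camera (adjusted p = 0.00392; adjusted p = 0.399 with an estimated correlation).

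Immediate-early genes, which respond within minutes to stimulation and to tissue dissociation, rose together: 14 of 20 rose, 0 fell and 6 did not pass, and 17 rose when adjusted over the list alone (median log2 change 1.03). Atf3 rose 2.63-fold (1.39 ± 0.16, adjusted p = 0.000874), Zfp36 2.66-fold, Klf6 2.41-fold and Klf4 2.24-fold. Camera called them up (adjusted p = 1.75e-24), with adjusted p = 0.0996 with an estimated correlation. Glucocorticoid targets had 7 of 15 members that rose, 0 that fell and 8 that did not pass, and 14 that rose when adjusted over the list alone. The glucocorticoid list was called up by camera (median 0.77; adjusted p = 5.28e-16; adjusted p = 0.0996 with an estimated correlation). Per1 rose 3.78-fold, Lcn2 3.08-fold and Dusp1 2.07-fold, and 6 of the 15 members are also held by other lists. In the circadian clock list 4 of 14 genes rose, 0 fell and 10 did not pass, while 7 rose and 3 fell when adjusted over the list alone. The clock list was called up by camera (adjusted p = 0.00252; adjusted p = 0.0996 with an estimated correlation). Besides Per1 they were Dbp (1.61 ± 0.33, adjusted p = 0.033), Per3 (adjusted p = 0.0322) and Bhlhe41 (adjusted p = 0.00493).

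Metabolic genes changed in several lists. Of 19 fatty acid oxidation and PPAR targets, 4 rose, 0 fell and 15 did not pass, and 8 rose and 1 fell when adjusted over the list alone. The fatty acid list was called up by camera (adjusted p = 0.00013; adjusted p = 0.122 with an estimated correlation). They were Pdk4, Acot1 (2.65-fold, adjusted p = 0.00382), Angptl4 (2.2-fold, adjusted p = 0.00695) and Cd36, a fatty acid transporter (2.84-fold, adjusted p = 0.00773). Of the 15 lipogenesis genes, 2 fell, 0 rose and 13 did not pass, with 2 falling and 1 rising when adjusted over the list alone. Scd1, a fatty acid desaturase, fell 2.91-fold (−1.54 ± 0.19, adjusted p = 0.00182) and Srebf1, a regulator of lipid synthesis, 1.6-fold (adjusted p = 0.023). Camera did not call the lipogenesis list (adjusted p = 0.84). In the list of glucose uptake and insulin signalling 4 of 20 genes rose, 0 fell and 16 did not pass, and 5 rose and 1 fell when adjusted over the list alone, without a call by camera (adjusted p = 0.108). These were Igf1r (1.9-fold, adjusted p = 0.00186), Txnip, a gene induced by glucose (2.01-fold, adjusted p = 0.00472), Irs2 (2.31-fold, adjusted p = 0.0106) and Igf1 (1.88-fold, adjusted p = 0.0494). Slc2a4, the insulin-responsive glucose transporter, had a log2 change of −0.65 ± 0.17 (adjusted p = 0.084) and Insr, the insulin receptor, 0.30 ± 0.12 (adjusted p = 0.249).

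In the glycolysis list Pfkfb3 rose 1.99-fold (adjusted p = 0.0308), Pfkm fell 1.54-fold (adjusted p = 0.0419) and 13 of 15 did not pass, with 1 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.171). Oxidative phosphorylation genes were called down by camera (median −0.25; adjusted p = 3.09e-07; adjusted p = 0.399 with an estimated correlation), although by limma 0 of 23 passed over all genes, 4 at an unadjusted p under 0.05, and 0 when adjusted over the list alone. The member with the smallest p, Ndufa1, had a log2 change of −0.52 ± 0.14 (adjusted p = 0.0876). Among 13 adipocyte genes 4 rose, 0 fell and 9 did not pass, and 7 rose when adjusted over the list alone. The adipocyte list was called up by camera (adjusted p = 6.85e-06; adjusted p = 0.0996 with an estimated correlation). Car3, a carbonic anhydrase abundant in fat and muscle, rose 9.63-fold (3.27 ± 0.33, adjusted p = 0.000462), Fabp4 2.59-fold, Pck1 2.37-fold and Retn 1.91-fold.

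Lcn2, an iron-binding acute phase protein, was the 1 of 19 inflammatory and NF-kB genes that rose (1.62 ± 0.17, adjusted p = 0.000608), with 0 falling and 18 not passing, and 6 rose when adjusted over the list alone. The inflammatory list was called up by camera (adjusted p = 0.00133; adjusted p = 0.399 with an estimated correlation). Of 19 macrophage and dendritic cell genes, 2 rose, 0 fell and 17 did not pass, and 5 rose when adjusted over the list alone (camera adjusted p = 0.00339; adjusted p = 0.399 with an estimated correlation). Cd68, a lysosomal protein (1.17 ± 0.21, adjusted p = 0.0205), and Mrc1, the mannose receptor (1.53 ± 0.33, adjusted p = 0.0397), rose, while Lyz2 stood at 1.76 ± 0.40 (adjusted p = 0.0506). The complement genes C4b (1.55 ± 0.31, adjusted p = 0.0309) and Serping1 (2.11 ± 0.47, adjusted p = 0.0454) rose, 0 of the 13 fell and 11 did not pass, with 6 rising and 1 falling when adjusted over the list alone. The complement list was called up by camera (adjusted p = 0.000872; adjusted p = 0.349 with an estimated correlation). C4b was also the 1 of 9 senescence genes that rose, with 0 falling, 8 not passing and 4 rising when adjusted over the list alone. The senescence list was called up by camera (adjusted p = 0.00908; adjusted p = 0.366 with an estimated correlation). Ifi205, an interferon-inducible gene outside the lists, rose 7.63-fold (2.93 ± 0.46, adjusted p = 0.0087). Fibroblast and matrix genes were called up by camera (median 0.68; adjusted p = 4.33e-05; adjusted p = 0.492 with an estimated correlation), while by limma 0 of 18 passed over all genes, 10 at an unadjusted p under 0.05, and 10 rose when adjusted over the list alone. Dcn stood at 1.44 ± 0.36 (adjusted p = 0.0691) and Fbln1 at 0.80 ± 0.18 (adjusted p = 0.0502).

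Xbp1, a regulator of secretory capacity, rose 1.53-fold (adjusted p = 0.025) and with Atf3 made up the 2 of 19 unfolded protein response genes that rose, 0 falling and 17 not passing, and 2 when adjusted over the list alone. The unfolded protein response list was called up by camera (adjusted p = 0.0118; adjusted p = 0.541 with an estimated correlation). Ltf, the antimicrobial lactotransferrin held by both the serous and the neutrophil list, rose 3.91-fold (adjusted p = 0.00951), and it was the 1 of 11 neutrophil genes that rose, over all genes and when adjusted over the list alone (camera adjusted p = 0.217). Gpx3, a secreted peroxidase, rose 2.88-fold (adjusted p = 0.0229), the 1 of 17 oxidative stress genes on either count (camera adjusted p = 0.251). Slc4a4, a bicarbonate transporter, rose 1.91-fold (adjusted p = 0.00773), the 1 of 22 saliva fluid secretion genes over all genes, and 3 rose when adjusted over the list alone (camera adjusted p = 0.19). Lymphocyte lists were not called: camera gave adjusted p = 0.108 for B cells, 0.251 for T cells, 0.0763 for plasma cells, 0.108 for follicle chemokines, 0.422 for NK cells, 0.108 for MHC class II and 0.796 for MHC class I. Xbp1 and an antigen receptor segment were the 2 of 12 plasma cell genes that rose over all genes, 0 falling and 10 not passing, and 3 rose and 1 fell when adjusted over the list alone. Cd3e stood at 0.96 ± 0.44 (adjusted p = 0.312), Ighm at 1.16 ± 0.45 (adjusted p = 0.239) and H2-Aa at 0.25 ± 0.19 (adjusted p = 0.546). Diabetic array 4 stood apart in lymphocyte genes, with a mean of 5.22 over the T cell list against 4.13 to 4.17 in the other diabetic arrays. Without it camera's direction turned from up to down for B cells (adjusted p = 0.579), T cells (0.254) and proliferation (0.328). The follicle list stayed up (camera adjusted p = 0.705). Among 22 antigen receptor segments 1 rose and 0 fell. Type I interferon genes (camera adjusted p = 0.108), interferon gamma targets (0.247), apoptosis genes (0.108), heat shock (0.118), proliferation (0.406), cholesterol synthesis (0.321), endothelium (0.8), skeletal muscle (0.171), nerve (0.795) and exocrine pancreas (0.19) were not called either.

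By limma, 271 of the 18826 genes passed an adjusted p of 0.05 between the diabetic and nondiabetic 21-week mice, of which 207 rose and 64 fell, and 148 changed at least 2-fold. In 269 of the 271 the arrays of the groups did not overlap, and over all genes tested 14.1% did not overlap where chance gives 5.71%. With quantile normalization 140 rose and 106 fell. Camera called 17 of 40 lists, 14 up and 3 down, and with an estimated correlation it called 0, with 7 at an unadjusted p under 0.05, while fry called 10. Fry called the glucose uptake list (fry adjusted p = 0.0463), which camera did not. Of the lists called by camera, fry did not call myoepithelium and senescence (fry adjusted p = 0.055 for each) or macrophages (0.0676). Nor did it call oxidative phosphorylation, matrix, duct, unfolded protein response and mucous genes (0.143 for each). With the preset correlation other splits of the same arrays gave up to 23 called lists. Median, mean and camera direction differed in sign for 3 lists, 0 of them called. The mucous and unfolded protein response calls were lost without 1 or other array. The count fell to 84 without nondiabetic 21-week array 3, 95 without diabetic array 3, 152 without diabetic array 2, 162 without nondiabetic 21-week array 1 and 175 without both nondiabetic array 3 and diabetic array 4. It was 0 (1887 at an unadjusted p under 0.05) with the mean of Amy1, Dnase1, Chia1 and Cst10 as a covariate, which nearly follows the diabetic group. Of the 62 named genes that passed, 39 passed with each array left out in turn. The fold of 6 of the 62 moved by over 1.5 times without 1 array: Chia1, Cst10 (140-fold) and Smr3a (402-fold) rose more and Serping1 less (2.86-fold) without nondiabetic array 3, and Klk1b22 (14.7-fold) and Crisp3 (5.92-fold) fell less without diabetic array 4. The other 23 were Acta2, Bpifa2, C4b, Cd68, Crisp3, Dbp, Fabp4, Galnt12, Gpx3, Igf1, Ltf, Mrc1, Myh11, Pck1, Per3, Pfkfb3, Pfkm, Retn, Serpinb11, Serping1, Smr3a, Srebf1 and Xbp1, 21 of which did not pass without nondiabetic 21-week array 3 (Crisp3, adjusted p = 0.0788).

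The age comparison set nondiabetic mice of 21 weeks (n = 3) against nondiabetic mice of 6 weeks (n = 3). The sample titles mark the former as SS, the latter as Young and the diabetic mice as T_S, without spelling these out. Age and whatever comes with it in this strain, such as gland inflammation, cannot be told apart here. Below, "with age" means the difference between these groups. Few single genes passed the test. Coch, the gene of the secreted protein cochlin, rose 3.25-fold (1.70 ± 0.16, adjusted p = 0.00279). Tll1, a metalloprotease that processes matrix proteins, fell 4.15-fold (−2.05 ± 0.23, adjusted p = 0.0057). Chn2, a regulator of Rac, fell 2.51-fold (−1.33 ± 0.17, adjusted p = 0.014) and Pim3, a survival kinase, fell 2.18-fold (−1.12 ± 0.14, adjusted p = 0.014). The remaining fallen gene, 2310057J18Rik, is an unnamed model outside the rule for named genes and was chosen after its values were seen.

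Antigen presentation and interferon lists shifted up with age. MHC class I and antigen processing genes had a median log2 change of 0.38 (camera adjusted p = 5.3e-13; adjusted p = 0.273 with an estimated correlation), with 0 of 14 past limma's test over all genes, 8 at an unadjusted p under 0.05, and 7 that rose when adjusted over the list alone. B2m, the light chain of class I molecules, stood at 1.21 ± 0.19 (adjusted p = 0.0658), Psmb8 at 0.98 ± 0.19 (adjusted p = 0.16), H2-K1 at 0.95 ± 0.30 (adjusted p = 0.572) and H2-Q4 at 0.73 ± 0.17 (adjusted p = 0.337). MHC class II genes had a median of 0.44 (camera adjusted p = 2.62e-08; adjusted p = 0.273 with an estimated correlation), with 0 of 9 past limma's test, 5 at an unadjusted p under 0.05, and 2 that rose when adjusted over the list alone. H2-Ab1 stood at 1.31 ± 0.25 and H2-Aa at 1.02 ± 0.20 (adjusted p = 0.16 for each). Type I interferon-stimulated genes had a median of 0.39 (camera adjusted p = 5.21e-10; adjusted p = 0.353 with an estimated correlation), with 0 of 18 past limma's test, 7 at an unadjusted p under 0.05, and 1 when adjusted over the list alone. Interferon gamma targets had a median of 0.37 (camera adjusted p = 2.26e-08; adjusted p = 0.273 with an estimated correlation), with 0 of 19, 6 unadjusted and 2 adjusted over the list alone. Usp18 stood at 1.13 ± 0.27 (adjusted p = 0.376), Mx2 at 0.75 ± 0.24 (adjusted p = 0.572) and Cxcl9 at 1.26 ± 0.33 (adjusted p = 0.481).

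The T, B and NK cell lists also shifted up with age, while plasma cells (camera adjusted p = 0.116) and follicle chemokines (0.254) were not called. T cell genes had a median log2 change of 0.45 (camera adjusted p = 3.81e-10; adjusted p = 0.414 with an estimated correlation), with 0 of 17 past limma's test, 4 at an unadjusted p under 0.05, and 1 that rose when adjusted over the list alone. Cd3g stood at 1.85 ± 0.35 (adjusted p = 0.16), Cd4 at 0.83 ± 0.28 (adjusted p = 0.577) and Cd3e at 0.82 ± 0.47 (adjusted p = 0.725). B cell genes had a median of 0.45 (camera adjusted p = 1.65e-05; adjusted p = 0.521 with an estimated correlation), with 0 of 15 past limma's test over all genes or adjusted over the list alone, 2 at an unadjusted p under 0.05. Cd79a stood at 0.98 ± 0.43 (adjusted p = 0.644) and Ighm at 1.18 ± 0.48 (adjusted p = 0.629). NK cell genes had a median of 0.33 (camera adjusted p = 2.91e-05; adjusted p = 0.273 with an estimated correlation), with 0 of 14 past limma's test, 4 unadjusted, and 1 adjusted over the list alone. Xcl1 stood at 0.63 ± 0.15 (adjusted p = 0.363). Cxcl13 stood at −0.52 ± 0.51 (adjusted p = 0.836).

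**Figure D2:**
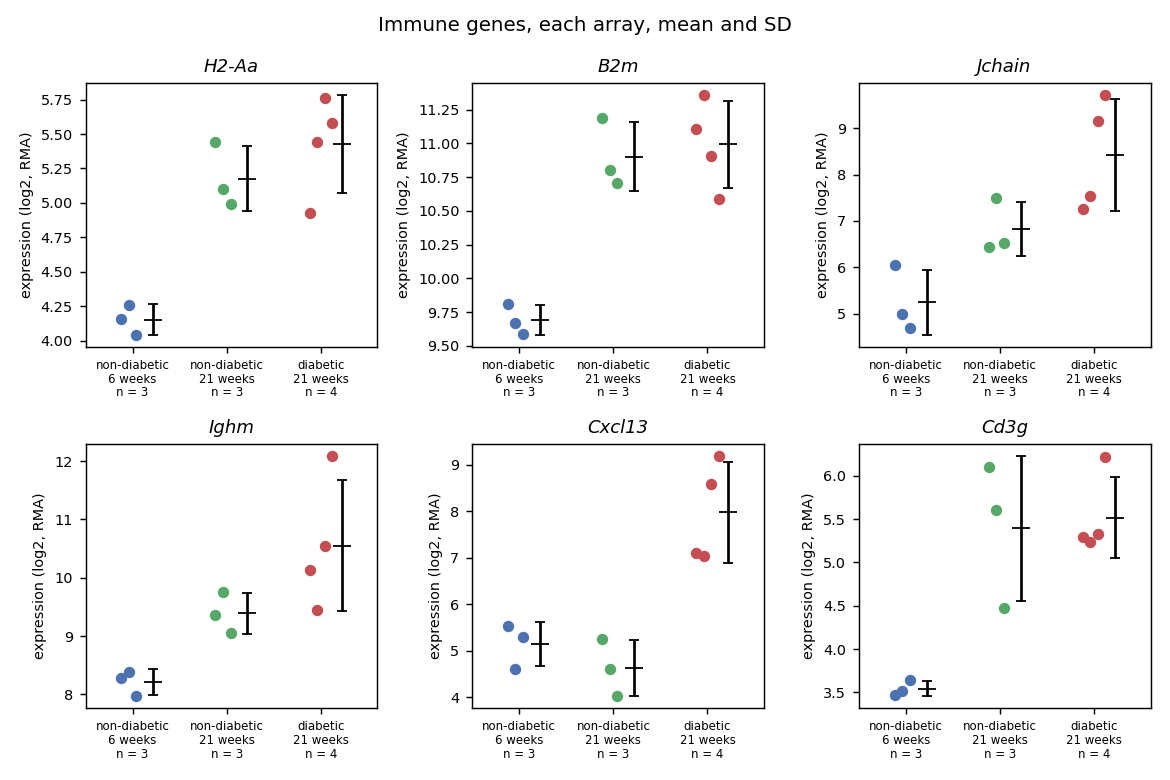
Expression (log2, RMA) of 6 immune genes (H2-Aa, B2m, Jchain, Ighm, Cxcl13, Cd3g) on each array, with group means and standard deviations, for 6-week nondiabetic (n = 3), 21-week nondiabetic (n = 3) and 21-week diabetic mice (n = 4). Cxcl13 averaged 7.98 in the diabetic and 4.63 in the nondiabetic 21-week arrays, and diabetic array 4 was the highest of its group for Cd3g (6.22).

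Granular convoluted tubule genes shifted up with age (median log2 change 0.77; camera adjusted p = 3.49e-11; adjusted p = 0.353 with an estimated correlation), with 0 of 17 past limma's test over all genes, 8 at an unadjusted p under 0.05, and 8 that rose when adjusted over the list alone. Klk1b24 stood at 1.52 ± 0.26 (adjusted p = 0.101), Egf at 1.18 ± 0.27 (adjusted p = 0.337), Klk1b8 at 1.86 ± 0.49 (adjusted p = 0.481) and Klk1b1 at 1.68 ± 0.43 (adjusted p = 0.477). Matrix and vessel genes shifted down. Fibroblast and matrix genes had a median of −0.55 (camera adjusted p = 1.87e-05; adjusted p = 0.521 with an estimated correlation), with 0 of 18 past limma's test, 5 at an unadjusted p under 0.05, and 1 that fell when adjusted over the list alone, Sparc, a matrix glycoprotein (−1.03 ± 0.24, adjusted p = 0.363 over all genes). The collagens Col3a1 and Col1a2 stood at −1.14 ± 0.38 (adjusted p = 0.577) and −0.94 ± 0.31 (adjusted p = 0.572). Endothelial genes had a median of −0.42 (camera adjusted p = 1.87e-05; adjusted p = 0.419 with an estimated correlation), with 0 of 14 past limma's test, 5 unadjusted, and 2 adjusted over the list alone. Tie1 stood at −0.59 ± 0.15 (adjusted p = 0.474), Cdh5 at −0.58 ± 0.17 (adjusted p = 0.506) and Kdr at −0.68 ± 0.26 (adjusted p = 0.629).

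Heat shock genes shifted down with age (median −0.40; camera adjusted p = 2.68e-05; adjusted p = 0.414 with an estimated correlation), with 0 of 12 past limma's test, 5 at an unadjusted p under 0.05, and 2 that fell when adjusted over the list alone. Hspe1 stood at −0.67 ± 0.18 (adjusted p = 0.481) and Hspb1 at −0.69 ± 0.20 (adjusted p = 0.518). Glucocorticoid targets (median −0.31; camera adjusted p = 0.00412; adjusted p = 0.567 with an estimated correlation) had 0 of 15 past limma's test, 4 unadjusted and 2 adjusted over the list alone. Pdk4 stood at −1.10 ± 0.24 (adjusted p = 0.307). Genes of glucose uptake and insulin signalling (median −0.18; camera adjusted p = 0.0157; adjusted p = 0.419 with an estimated correlation) had 0 of 20 past limma's test, 3 unadjusted and 1 adjusted over the list alone, Txnip (−0.80 ± 0.15, adjusted p = 0.16 over all genes). Slc2a4 stood at 0.34 ± 0.18 (adjusted p = 0.699) and Insr at −0.02 ± 0.13 (adjusted p = 0.984). Senescence genes (median −0.26; camera adjusted p = 0.045; adjusted p = 0.486 with an estimated correlation) had 0 of 9 past limma's test, 1 unadjusted and 1 adjusted over the list alone, Cdkn1a (−0.68 ± 0.19, adjusted p = 0.481 over all genes). Serous cargo genes (median −0.33; camera adjusted p = 0.00481; adjusted p = 0.419 with an estimated correlation) had 0 of 19 past limma's test over all genes or adjusted over the list alone, 5 unadjusted. Dcpp1, grouped below with genes of the sublingual gland, stood at −3.26 ± 1.27 (adjusted p = 0.629) and Amy1 at −1.44 ± 0.58 (adjusted p = 0.629). Dcpp1 varied within the older group, with 3.11, 10.79 and 6.74 in the nondiabetic 21-week arrays against 10.19, 10.74 and 9.48 in the 6-week arrays. Duct epithelium genes (median 0.10; camera adjusted p = 0.012; adjusted p = 0.521 with an estimated correlation) had 0 of 19 past limma's test on either count or at an unadjusted p under 0.05. Aqp5 stood at −0.02 ± 0.17 (adjusted p = 0.983) and Bhlha15 at −0.19 ± 0.19 (adjusted p = 0.84).

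By limma, 5 of 18826 genes passed for age, 1 rising and 4 falling, with 1406 at an unadjusted p under 0.05. The arrays of the groups did not overlap in any of the 5, and over all genes 13.8% did not overlap where chance gives 10%. Further genes named by smallest p without passing were Slfn2 (1.51 ± 0.24), Naip6 (1.26 ± 0.20) and Ddah1 (−0.96 ± 0.15), each at adjusted p = 0.0658, Ccn1 (−0.73 ± 0.12, adjusted p = 0.0945), Adgrl2 (−0.86 ± 0.15, adjusted p = 0.101) and Sohlh2 (0.93 ± 0.17, adjusted p = 0.16). Naip6 and Sohlh2 lay below the 25th percentile on all 3 of the 6-week arrays. Quantile normalization gave 2 rising and 4 falling, and median centring 3 and 4. Camera called 16 lists, 9 up and 7 down, and with an estimated correlation 0, with 5 at an unadjusted p under 0.05. Fry called 0, with 6 unadjusted, and other splits of the same arrays gave up to 13 lists with the preset correlation. Median, mean and camera direction differed in sign for 11 lists, 0 of them called, and the 24 uncalled lists had camera adjusted p-values of 0.116 to 0.976. Leaving out 1 array could end the call of the serous, senescence, glucocorticoid, duct, glucose uptake or matrix list. The count was 10 without nondiabetic 21-week array 2, 8 without nondiabetic 21-week array 3, 2 without 6-week array 1, 1 without 6-week array 3 and 39 without both nondiabetic array 3 and diabetic array 4. It was 0 (1377 at an unadjusted p under 0.05) in a fit of these 6 arrays alone. Of the 4 named genes that passed, Coch passed with each array left out in turn. Tll1 did not pass without 6-week array 3, Pim3 did not without any 1 of the 6-week arrays, and Chn2 did not without any 1 of these or without nondiabetic 21-week array 1.

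The third comparison set the diabetic 21-week mice (n = 4) against the 6-week nondiabetic mice (n = 3), so age and diabetes differed together. Jchain, which joins secreted antibody chains, rose 9.04-fold (3.18 ± 0.54, adjusted p = 0.0145), Ighm, the IgM heavy chain, 5.06-fold (2.34 ± 0.45, adjusted p = 0.0284) and H2-Aa, a class II chain, 2.42-fold (1.27 ± 0.18, adjusted p = 0.00651). Clock genes moved in opposite directions, with Arntl down 7.67-fold (−2.94 ± 0.43, adjusted p = 0.00668), Npas2 down 4.47-fold (−2.16 ± 0.27, adjusted p = 0.00317) and Bhlhe41 up 2.42-fold (adjusted p = 0.00377). Klk1b8, close to background on 3 of the 4 diabetic arrays, fell about 18.4-fold (−4.21 ± 0.46, adjusted p = 0.00154) and Chia1 rose 22.7-fold (4.51 ± 0.76, adjusted p = 0.0138). The Chia1 rise was 46-fold without 6-week array 1.

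Of the 12 plasma cell and immunoglobulin genes, 4 rose, 1 fell and 7 did not pass, and 6 rose and 1 fell when adjusted over the list alone. The plasma cell list was called up by camera (adjusted p = 0.00146; adjusted p = 0.251 with an estimated correlation). Xbp1 rose 1.47-fold (adjusted p = 0.0369), and Derl3, a gene of protein degradation in the endoplasmic reticulum, fell 1.83-fold (−0.87 ± 0.13, adjusted p = 0.00713). Of 22 antigen receptor segments, 8 rose and 0 fell (median 2.04). Among 14 MHC class I and antigen processing genes 3 rose, 0 fell and 11 did not pass, and 6 rose when adjusted over the list alone (camera adjusted p = 2.89e-08; adjusted p = 0.13 with an estimated correlation). B2m rose 2.47-fold (1.30 ± 0.18, adjusted p = 0.00473), H2-Q4 1.83-fold and Psmb8, a subunit of the immunoproteasome, 1.84-fold. Of 9 MHC class II genes 2 rose, 0 fell and 7 did not pass, and 7 rose when adjusted over the list alone (camera adjusted p = 8.78e-09; adjusted p = 0.13 with an estimated correlation). H2-Ab1 rose 2.8-fold (adjusted p = 0.0104). Psmb8 was the 1 of 19 interferon gamma targets that rose over all genes, and 12 rose when adjusted over the list alone. The interferon gamma targets list was called up by camera (adjusted p = 1.37e-08; adjusted p = 0.13 with an estimated correlation). Zbp1, a sensor of nucleic acids (adjusted p = 0.0328), was the 1 of 18 type I interferon genes that rose on either count. The type I interferon list was called up by camera (adjusted p = 0.00058; adjusted p = 0.364 with an estimated correlation).

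Cd3g, a chain of the T cell receptor complex, rose 3.93-fold (1.97 ± 0.33, adjusted p = 0.0122), the 1 of 17 T cell genes that rose over all genes, 0 falling and 16 not passing, while 9 rose when adjusted over the list alone (camera adjusted p = 1.25e-09; adjusted p = 0.215 with an estimated correlation). Cd3e stood at 1.78 ± 0.44 (adjusted p = 0.0713). B cell genes were called up (median 0.56; camera adjusted p = 3e-07; adjusted p = 0.251 with an estimated correlation), with 0 of 15 past limma's test over all genes, 8 at an unadjusted p under 0.05, and 8 that rose when adjusted over the list alone. Bank1 stood at 1.07 ± 0.29 (adjusted p = 0.102) and Cd79a at 1.34 ± 0.40 (adjusted p = 0.131). Diabetic array 4 had a mean of 5.30 over the B cell list against 3.83 to 4.08 in the other diabetic arrays. Cxcl13 rose 7.09-fold (2.83 ± 0.48, adjusted p = 0.014), the 1 of 13 follicle chemokine genes over all genes, and 4 rose when adjusted over the list alone. The follicle list was called up by camera (adjusted p = 0.00267; adjusted p = 0.251 with an estimated correlation). For that list too diabetic array 4 was high, with a mean of 5.01 against 4.06 to 4.08, and without it camera gave adjusted p = 0.0262. NK cell genes were called up (camera adjusted p = 0.0106; adjusted p = 0.251 with an estimated correlation) with 0 of 14 past limma's test, 6 unadjusted, and 5 adjusted over the list alone. Macrophage and dendritic cell genes were called up (camera adjusted p = 8.78e-06; adjusted p = 0.14 with an estimated correlation) with 0 of 19 past limma's test, 8 unadjusted, and 5 adjusted over the list alone. Lcn2 rose 2.43-fold (adjusted p = 0.00473), the 1 of 19 inflammatory genes over all genes, while 6 rose and 1 fell when adjusted over the list alone. The inflammatory list was called up by camera (adjusted p = 1.73e-05; adjusted p = 0.16 with an estimated correlation). Ltf rose 4.08-fold (adjusted p = 0.00919), the 1 of 11 neutrophil genes on either count. The neutrophil list was called up by camera (adjusted p = 0.0256; adjusted p = 0.215 with an estimated correlation). Complement genes were called up (camera adjusted p = 4.81e-05; adjusted p = 0.142 with an estimated correlation) with 0 of 13 past limma's test, 7 unadjusted, and 5 adjusted over the list alone.

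Tubule genes fell here too, 10 of 17, with 0 rising and 7 not passing, and 14 when adjusted over the list alone. The tubule list was called down by camera (median −1.51; adjusted p = 2.48e-15; adjusted p = 0.13 with an estimated correlation). Klk1b22 fell 9.9-fold, Klk1b9 7.91-fold, Klk1b16 7.83-fold, Crisp3 6.76-fold, Klk1b1 about 6.56-fold (2 of 4 diabetic arrays below the 25th percentile), Klk1b11 5.52-fold and Klk1b21 3.77-fold, and Egf stood at −1.10 ± 0.25 (adjusted p = 0.0515). Serous cargo had 5 of 19 genes that rose, 0 that fell and 14 that did not pass, and 9 rose and 3 fell when adjusted over the list alone (camera adjusted p = 2e-05; adjusted p = 0.14 with an estimated correlation). Cst10 rose 16.3-fold, Dnase1 16.1-fold and Amy1 13.8-fold. The parotid cargo score was 10.28 to 10.74 in the diabetic arrays and 4.85 to 8.66 in the 6-week arrays. Bpifb1 rose 8.64-fold, Odam 6.47-fold, Sel1l3 5.11-fold and Serpinb11 5.05-fold, while Fads2b fell 6.92-fold and Tll1 5-fold (adjusted p = 0.000888). Aqp5 stood at 0.07 ± 0.16 (adjusted p = 0.881) and Bhlha15 at −0.47 ± 0.18 (adjusted p = 0.232). Duct genes were not called (camera adjusted p = 0.191). Scnn1b fell 1.85-fold (adjusted p = 0.0133), Cldn4, a tight junction protein, rose 1.66-fold (adjusted p = 0.0458) and 17 of 19 did not pass, with 3 rising and 5 falling when adjusted over the list alone. Slc4a4 rose 1.73-fold (adjusted p = 0.0209), the 1 of 22 fluid secretion genes over all genes and 1 of 2 when adjusted over the list alone (camera adjusted p = 0.0779).

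Immediate-early genes rose in 13 of 20 cases, with 0 falling and 7 not passing, and in 16 when adjusted over the list alone (median 0.94; camera adjusted p = 3.03e-24; adjusted p = 0.13 with an estimated correlation). Atf3 rose 2.81-fold, Zfp36 2.74-fold, Klf6 2.26-fold and Ier2 1.98-fold. Of 15 glucocorticoid targets 7 rose, 0 fell and 8 did not pass, and 9 rose when adjusted over the list alone (camera adjusted p = 2.84e-11; adjusted p = 0.13 with an estimated correlation). Dusp1 rose 2.01-fold. The clock list had 6 of 14 genes that rose, 2 that fell and 6 that did not pass, and 8 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.000116; adjusted p = 0.13 with an estimated correlation). Per3 rose 2.5-fold. Fatty acid oxidation and PPAR targets had 4 of 19 that rose, 0 that fell and 15 that did not pass, and 8 rose when adjusted over the list alone (camera adjusted p = 0.000194; adjusted p = 0.13 with an estimated correlation). Angptl4 rose 2.09-fold, Pdk4 2.07-fold, Cpt1a 1.74-fold and Ech1 1.66-fold. Cycs, cytochrome c, fell 1.88-fold (−0.91 ± 0.20, adjusted p = 0.0472), the 1 of 23 oxidative phosphorylation genes on either count. The oxidative phosphorylation list was called down by camera (adjusted p = 1.58e-06; adjusted p = 0.323 with an estimated correlation). Car3 rose 8.18-fold (3.03 ± 0.33, adjusted p = 0.00137), 1 of the 3 of 13 adipocyte genes that rose, 0 falling and 10 not passing, with 4 rising when adjusted over the list alone. The adipocyte list was called up by camera (adjusted p = 2.3e-05; adjusted p = 0.13 with an estimated correlation). In lipogenesis Dgat2 rose 1.5-fold (adjusted p = 0.0285) and Scd1 fell 1.9-fold (adjusted p = 0.035), 13 of 15 did not pass, and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.53). Igf1r rose 1.67-fold (adjusted p = 0.00959), the 1 of 20 genes of glucose uptake and insulin signalling over all genes, with 3 rising and 2 falling when adjusted over the list alone (camera adjusted p = 0.854). Txnip stood at 0.21 ± 0.14 (adjusted p = 0.53), Slc2a4 at −0.31 ± 0.17 (adjusted p = 0.423) and Insr at 0.28 ± 0.12 (adjusted p = 0.28).

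Acta2 rose 2.27-fold (adjusted p = 0.0365), the 1 of 9 myoepithelial and basal cell genes on either count. The myoepithelial list was called up by camera (adjusted p = 0.00115; adjusted p = 0.215 with an estimated correlation). Endothelial genes were called down (median −0.36; camera adjusted p = 0.00177; adjusted p = 0.364 with an estimated correlation) with 0 of 14 past limma's test, 7 of them at an unadjusted p under 0.05, and 6 falling and 1 rising when adjusted over the list alone. Kdr stood at −1.06 ± 0.24 (adjusted p = 0.0553). Sparc fell 2.14-fold (adjusted p = 0.0355), the 1 of 18 matrix genes on either count, in a list that was not called (camera adjusted p = 0.276). Atf3 and Xbp1 were the 2 of 19 unfolded protein response genes that rose over all genes, and 3 rose and 1 fell when adjusted over the list alone. The unfolded protein response list was called up by camera (adjusted p = 0.0233; adjusted p = 0.509 with an estimated correlation). Oxidative stress genes (camera adjusted p = 0.0175; adjusted p = 0.215 with an estimated correlation) had 0 of 17 past limma's test, 7 at an unadjusted p under 0.05, and 3 rising and 1 falling when adjusted over the list alone. Proliferation genes (camera adjusted p = 0.0373; adjusted p = 0.534 with an estimated correlation) had 0 of 18 past limma's test, 2 unadjusted and 1 adjusted over the list alone. That call leaned on diabetic array 4, whose mean over the proliferation list was 4.49. The other diabetic arrays had 3.78 to 3.85 and the 6-week arrays 3.73 to 3.89. Camera gave adjusted p = 0.76 without diabetic array 4 and 0.137 without 6-week array 3. The 14 uncalled lists had camera adjusted p-values of 0.0711 to 0.854, among them heat shock (0.0711), mucous and sublingual genes (0.16), skeletal muscle (0.31), nerve (0.561) and exocrine pancreas (0.252).

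**Figure D3:**
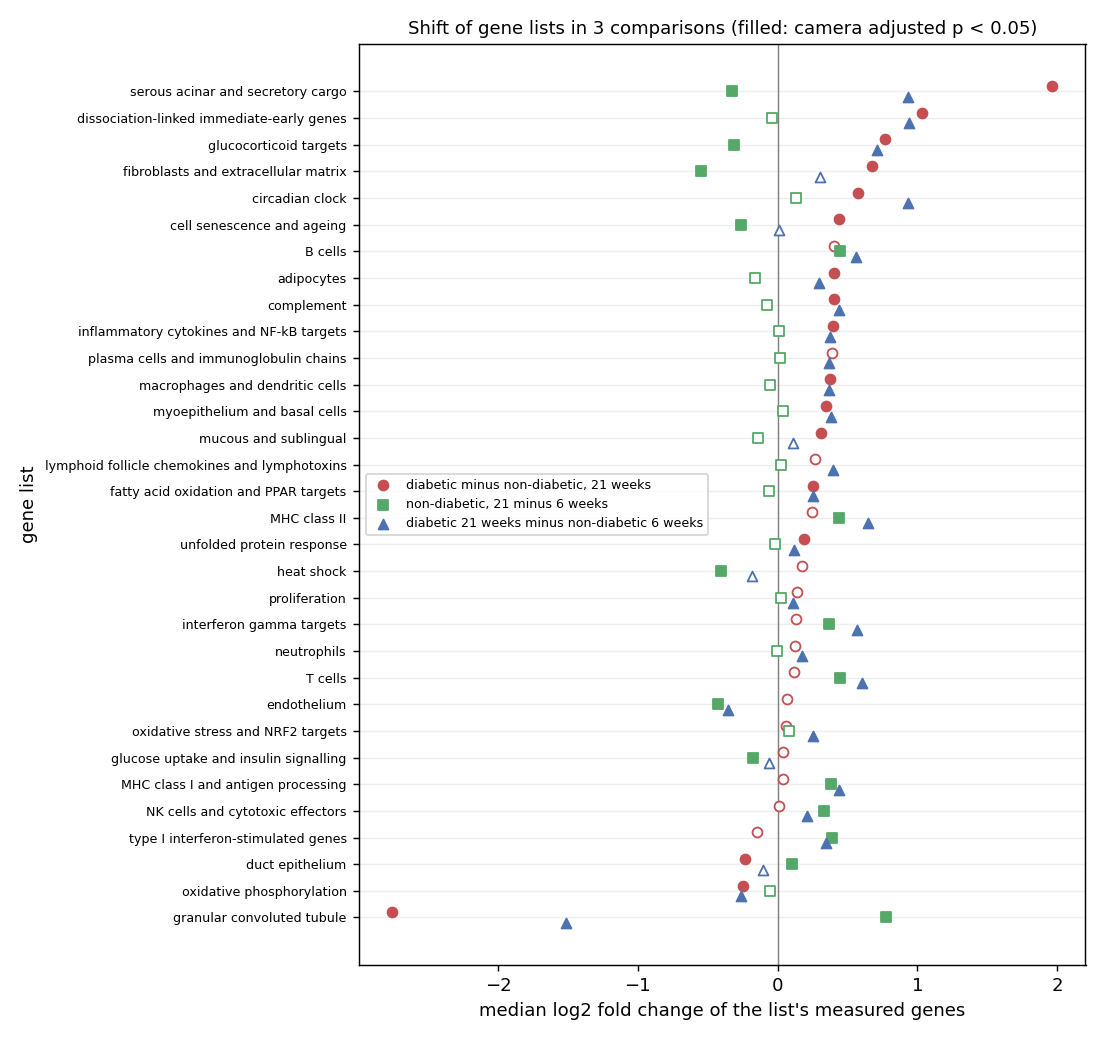
Median log2 change of each gene list called by camera in at least 1 of the 3 comparisons (x axis, log2 scale), with filled marks where camera's adjusted p was under 0.05 with the preset correlation. Granular convoluted tubule genes lie at −2.76 for diabetes, 0.77 for age and −1.51 for both together. With an estimated correlation 0 lists were called, and 7, 5 and 12 had an unadjusted p under 0.05, while fry called 10, 0 and 13.

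By limma, 272 of 18826 genes passed for age and diabetes together, 170 rising and 102 falling, and 128 changed at least 2-fold. The arrays of the groups did not overlap in any of the 272, and over all genes 16.7% did not overlap where chance gives 5.71%. With quantile normalization 185 rose and 175 fell. Camera called 26 lists, 23 up and 3 down, with an estimated correlation 0 (12 at an unadjusted p under 0.05), and fry called 13. Other splits of the same arrays gave up to 24 lists with the preset correlation. Median, mean and camera direction differed in sign for 2 lists, 0 of them called. Calls of the unfolded protein response, neutrophil and proliferation lists were lost without 1 or other array. The count was 48 without 6-week array 3, 68 without 6-week array 2, 98 without 6-week array 1, 91 without diabetic array 3, 155 without diabetic array 2, 505 without both nondiabetic array 3 and diabetic array 4, and 672 with array weights. Without 6-week array 1 the folds of Chia1, Cst10 (31.4), Dnase1 (28.9), Amy1 (25) and Bpifb1 (15) were over 1.5 times as large. Those of Klk1b22 (5.82) and Crisp3 (4.45) were smaller by over 1.5 times without diabetic array 4. Of the 55 named genes that passed, 19 passed with each array left out in turn, namely Dnase1, Amy1, Car3, Odam, Klk1b8, Klk1b9, Arntl, Fads2b, Tll1, Npas2, B2m, Bhlhe41, Atf3, Zfp36, Klf6, Ier2, Lcn2, Dusp1 and Derl3. The other 36 each failed to pass without 6-week array 3.

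Coch rose and Tll1 fell both with age and with age and diabetes together. These were the 2 genes shared by both sets of calls, 1 rising where independent sets would share 0.00903 and 1 falling where they would share 0.0217. The simulated unchanged groups set against the same 6-week arrays shared 0 on average in 50 simulations. With no change in any group few genes are expected to pass, so this count does not show what common controls alone would share. Over all genes the log2 changes of these comparisons had a correlation of 0.307 against 0.534 in the simulated groups and a covariance of 0.0231 against 0.0208. Genes are not independent replicates. The 3 young arrays could not be divided into separate controls of at least 2 each, so part or all of the sharing may come from the common controls.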

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

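The tests of the 3 patterns weighed here, and the parotid cargo and clock scores behind them, were chosen after the results were seen, while the rule for arrays far from the others of their group was set before.

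Cargo genes abundant in the parotid gland (Amy1, Dnase1, Chia1, Cst10, Smr3a, Bpifa2) were higher in the diabetic than in the nondiabetic 21-week arrays. Nondiabetic 21-week array 3 did not carry the difference, since 6 of these 6 genes stayed past the threshold without it. A larger share of parotid tissue in the diabetic samples may account for it. In each nondiabetic group the same array was the highest for every one of the 6 genes, 12 of 12 tops, as a varying gland mix would give. In the 21-week group it was array 3, which stands apart. Anything else that moves these genes together would give this too, so the tops do not single out gland mix. Diabetes itself stays open: all 6 genes were higher in all 4 diabetic than in all 6 nondiabetic arrays, but they were chosen for that rise, so this tests nothing, and gland mix and diabetes cannot be told apart.

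Granular convoluted tubule genes were lower in the diabetic arrays, with a log2 difference of −3.55 ± 0.48 for the mean of the 12 that fell. Nondiabetic 21-week array 3 did not carry the fall, as 10 of the 12 genes stayed past the threshold without it. Parotid in place of submandibular tissue could not be settled: a straight-line fit on the cargo score, run first, left −3.79 ± 1.23 with a slope of 0.04 ± 0.21 where −0.65 would be needed, but replacement bends on the log2 scale and would lower the tubule score of the nondiabetic arrays by only 0.02 to 0.40. Tested on that expected fall, between nondiabetic arrays of one group, the tubule score had a slope of 0.51 ± 1.23, where 1 is the value if it is the cause and 0 if not. A smaller share of submandibular tissue could not be settled either, because Pip, Prol1 and Scgb2b27 differed by −0.164 on average, but Scgb2b27 is itself in the tubule list and all 3 lay between 11.99 and 12.68, near the lowest array maximum of 13.13, where a fall may be hidden; an effect of diabetes on the tubule cells stays open, untested.

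Immediate-early genes were higher in the diabetic arrays, with a score difference of 0.98 ± 0.14. Another time of day at collection could not be settled. With the clock score as a covariate the difference was 0.863 ± 0.24 and the slope was 0.07 ± 0.13 where 0.65 would be needed. That slope comes only from the spread of the clock score within groups. If each group was collected at its own time, this spread need not carry the effect of time. A longer or harsher dissociation of the diabetic samples could not be told apart from diabetes, as no handling times are given in the sources used here and the heat shock list, which dissociation may also raise, had a camera adjusted p of 0.118. Diabetes itself was not tested separately from handling.

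Diabetic array 4 lay far from the other 3 diabetic arrays in 12 of 159 series tested (119 named genes and 40 list means), and 13 series in all held such an array where chance marks about 1 in 20 groups, or 7.95. Its Cd3g value was 6.22 against 5.23 to 5.33 in the others. Cdkn1a was 6.11 against 5.53 to 5.60. Its low values were Egf at 6.73 against 7.59 to 7.62, Galnt12 at 4.58 against 5.34 to 5.40, Sel1l3 at 5.47 against 7.15 to 7.32, Serpinb11 at 5.90 against 7.15 to 7.40 and Sparc at 5.19 against 5.44 to 5.48. The mean over the B cell list was 5.30 against 3.83 to 4.08, over the T cell list 5.22 against 4.13 to 4.17, over the lymphoid follicle list 5.01 against 4.06 to 4.08, over the proliferation list 4.49 against 3.78 to 3.85 and over the mucous and sublingual list 5.33 against 5.86 to 5.91. For diabetic array 2 the mean over the MHC class I list was 6.17 against 5.83 to 5.87.

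Probe sets left out of the comparisons also held a signal when every probe set was fitted. Of those with several gene symbols, 10 passed the threshold for diabetes and 10 for age and diabetes together. Of those unnamed here, 28 passed for diabetes, 1 for age and 17 for both together.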

How the results depend on the processing

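Leaving out both arrays that stand apart and the parotid cargo covariate were tests chosen after the results were seen; the others, the splits included, were planned. The diabetes count of 271 stayed within 1.5 times itself with no filter (232), a filter at the median (364), mean probe sets (269), trended and robust variance (364), array weights (367), quantile normalization (246), median centring (296) and the replicate block (204, of which 152 were among the 271). The replicate numbers do not pair the mice (9 same-numbered pairs had correlations of −0.12 to 0.066). It was 101 probe sets with every probe set, 161 with only the 2 groups compared, 69 at an adjusted p under 0.01, 148 at 2-fold or more, 175 without both arrays that stand apart, 0 with the parotid cargo covariate (1887 at an unadjusted p under 0.05 by limma). It was 84 to 268 with each array left out. The age count of 5 was 2 with every probe set, 0 with only the 2 groups compared (1377 at an unadjusted p under 0.05 by limma), 12 with trended and robust variance, 18 with array weights, 3 at an adjusted p under 0.01, 39 without both arrays that stand apart, and 1 to 10 with each array left out. The count of 272 for age and diabetes together was 74 with every probe set, 672 with array weights, 58 at an adjusted p under 0.01, 128 at 2-fold or more, 505 without both arrays that stand apart, and 48 to 393 with each array left out. Stricter thresholds lower the counts by construction. Why the counts were lower with every probe set was not tested. The number of arrays alone does not set the count. For diabetes it was 162, 218 or 84 without nondiabetic 21-week array 1, 2 or 3. For age and diabetes together it rose to 393 without nondiabetic 21-week array 3 and to 505 without both arrays that stand apart. For the arrays left out and the other settings the cause was not tested. The called lists numbered 17, 16 and 26 for diabetes, age and both, 0, 0 and 0 with an estimated correlation (7, 5 and 12 unadjusted), 10, 0 and 13 by fry. They were 18, 17 and 25 with the replicate block, 22, 16 and 27 with no filter, 17, 14 and 25 without both arrays that stand apart, and 15 to 22, 13 to 17 and 25 to 29 with each array left out. With the parotid cargo covariate 5 diabetes genes reversed without passing: Smr3a (−3.52), Chia1 (−0.39), Cst10 (−0.69), Bpifb1 (−0.25) and Bpifa2 (−1.82); Chia1 and Cst10 are part of that covariate, the mean of Amy1, Dnase1, Chia1 and Cst10, and Smr3a and Bpifa2 were picked as cargo with them. Of the planned settings, 9 kept the threshold, all arrays of the groups compared and 1 value per gene. Of the named genes past the threshold, 41 of 62 for diabetes, 0 of 4 for age and 35 of 55 for both stayed past it in all 9. With the parotid cargo covariate 0 of the diabetes genes stayed past it. The shared calls of age and of both together stayed at 2 with an adjusted p under 0.01.

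Among splits of the same arrays, an accidental split of mice is unlikely to give the diabetes gene count (real 271, highest other 27, 1 of 35 splits as large). The same holds for age and diabetes together (272 and 21, 1 of 35), and both of those other splits put diabetic array 4 with the opposite group. A share of 1 of 35 is the smallest that these splits can give. For age the splits are too few for a share under 0.05 (real 5, highest other 1; 1 of 10). For called lists, chance cannot be excluded for diabetes (17 and 23, 5 of 35 splits as large). For both together the real split called the most lists (26, 1 of 35), but other splits called up to 24. An estimated correlation called 0 lists there, so chance is not excluded for both together either. For age the splits are too few for a share under 0.05 (16 and 13, 1 of 10). Signals near an array's 25th percentile are close to background, where arrays show small changes least well.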

Other observations

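The tests below were chosen after the results were seen. Chemokine genes, some of them also list members, were examined in the same limma fit, and 4 of the 33 measured rose in the diabetic against the nondiabetic 21-week arrays: Cxcl13, Ccl9 (1.63 ± 0.23, adjusted p = 0.00415), Ccl11, which draws eosinophils (1.67 ± 0.35, adjusted p = 0.0334), and Ccl6 (adjusted p = 0.042). In the diabetic against the 6-week arrays 3 rose, Cxcl13, Ccl9 (adjusted p = 0.0332) and Ccl8 (1.60, adjusted p = 0.0408), and for age 0 passed by limma, with 5 at an unadjusted p under 0.05. Of 11 acute phase genes measured, 5 rose with diabetes: Lcn2, Clu (1.03 ± 0.16, adjusted p = 0.00773), Serpina3n (adjusted p = 0.015), Lbp (adjusted p = 0.0151) and Cp (adjusted p = 0.0479). With age and diabetes together 3 rose, Lcn2, Clu (1.26) and Serpina3n (1.25), and with age 0 passed, with 0 at an unadjusted p under 0.05. These genes were chosen after their values were seen.

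Genes of the sublingual gland (Muc19, Dcpp1, Dcpp2 and Dcpp3) varied between mice of one group, with a mean of 3.70, 10.37 and 6.18 in the nondiabetic 21-week arrays. Their mean was 10.74, 10.65, 10.83 and 10.28 in the diabetic arrays and 9.26, 9.93 and 8.29 in the 6-week arrays. Nondiabetic 21-week array 2, at 10.37, lay within the diabetic range. The gland taken is not given in the sources used here, so gland mix and diabetes cannot be told apart for these genes either. By limma 0 of the 4 passed in any comparison, with 4, 2 and 1 at an unadjusted p under 0.05 for diabetes, age and both.

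Clock genes differed between the diabetic and the nondiabetic 21-week arrays. A score of the Per arm minus the Arntl arm was higher by 1.5 in the diabetic arrays, the highest difference in another split being 1.29. The two-sided exact permutation p was 0.0286 over 35 splits, the smallest that these splits can give. The score was chosen after the results were seen, so this p-value is not a test of the difference. Another time of day at collection could give this difference, and diabetes itself could too, since the time of collection is not given in the sources used here.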
